A study of Mus musculus with 2 samples.

How the data were processed

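Single-cell RNA was measured in whole, dissociated mouse lung with a probe-based kit for fixed cells (10x Genomics Flex), in which pairs of probes are ligated on each transcript and unique molecular identifiers (UMIs) are counted per cell. The series is about chronic graft-versus-host disease (cGVHD), in which donor immune cells attack the tissues of a transplant recipient, and about inhibition of BET proteins, the bromodomain readers of acetylated histones. Per the labels, 1 library pooled several lungs with probe barcodes, among them cGVHD sample 1, and a second library held cGVHD sample 2 alone. The labels do not state that the 2 samples come from different animals, and they were taken here as 1 group of 2 lungs, called lung 1 and lung 2. The count matrices of the other arms were not used here, so no arm is compared with another.

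The deposited matrices hold raw UMI counts per gene and cell barcode, without normalization, for barcodes that the authors' pipeline called as cells (Cell Ranger 8.0.0, genome build mm10, per the labels). Their values were checked to be whole numbers. The matrices cover 19059 genes, and the 4 gene lists read were identical. In lung 1, 1 of 13579 barcodes had no usable name and was not analysed. Lung 1 held 59264940 UMIs and lung 2 held 120439854 UMIs, with medians of 3330.5 and 5697.5 UMIs and of 1676 and 2645 genes per barcode.

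Cells were kept with at least 200 genes and 500 UMIs, which 2 barcodes of lung 1 and 43 of lung 2 did not reach. Scrublet (in scanpy 1.11.5, run on each library) predicted 1401 doublets in lung 1 (10.3%) and 406 in lung 2 (3.78%), and these were removed. This left 12175 and 10327 cells with 48780215 and 113985087 UMIs. Counts were scaled to 10000 per cell and log-transformed, 3000 variable genes were scaled within each library, and 40 principal components and 20 neighbours fed Leiden clustering (leidenalg 0.10.2) at resolution 1. Genes of the 17 lists (225 genes, 222 of them on the panel) were kept out of the clustering features. The lists and 36 marker sets, the tests between classes, the rule for the genes named in the text and all alternatives except those marked as added later were fixed before the data were examined. Tests of explanations in the closing section were in part chosen after the result was seen, as marked there.

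The 45 clusters were named from the fixed markers, with levels in CPM (UMI counts scaled to the same library total). A cluster took the class whose markers had the highest mean log2 fold over clusters of other classes (pseudocount 5 CPM), given a mean of at least 1 and at least 3 markers over 1. It stayed unnamed if markers of a second lineage scored at least 66.7% of the best, if at least 5 of its 10 leading genes were mitochondrial, if at least 2 were platelet or granulocyte-monocyte progenitor genes, if it was shallow without a leading marker, or if another class had more markers among the leading genes. This naming rule, unlike the markers, was set after the clusters had been seen and is the last of 4 forms tried. The other forms set a cluster against the mean of all others, against their median, or against other classes without a second search for markers of another lineage, and they are kept as alternatives. The rule named 38 clusters in 20 classes, and 7 clusters stayed unnamed. Every class name below means cells that resemble that type by markers.

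UMIs were summed per lung and class, and a class entered a test with at least 30 cells in each lung. Classes were compared with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) with lung as a block, TMM scaling and the filterByExpr gene filter, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. This leaves 1 residual degree of freedom per gene, and the spread is mostly borrowed across genes. Counts of list genes are given over all genes tested and adjusted over the list alone. Since classes were built from the same cells, the number of differing genes between them is partly fixed by the clustering. List genes entered neither the clustering nor, apart from the shared cycling markers, the marker sets used for names. Levels are CPM of the summed counts, given as mean ± SD over the 2 lungs. Standard errors of log2 folds were derived from the edgeR test, as the absolute log2 fold over the square root of its F value. They are approximate, above all for large folds that rest on few UMIs. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and ratios of low counts carry exact 95% counting intervals. All such intervals cover counting error only, not differences between animals. Low-count ratios between classes use UMIs summed over both lungs without the lung pairing, so they can mix class and lung differences. Lungs were set against each other as values without a test.

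The test was checked on simulated counts with the fitted spread, in 10 draws with 200 changed genes each. A 4-fold change was found in 96.9%, 96.7% and 84.1% of changed genes for interstitial against alveolar macrophages, interstitial macrophages against classical monocytes, and adventitial against alveolar fibroblasts. A 2-fold change was found in 60.3%, 70.1% and 24.7%. False calls made up 25.6%, 15.1% and 4.09% of all simulated calls where 5% was nominal. Of unchanged genes, edgeR gave 5.34%, 5.29% and 4.52% an unadjusted p under 0.05. The 200 changed genes of a draw are far fewer than the genes called in the data, so these shares of false calls cannot be carried over. The macrophage comparisons may hold more false calls than their threshold states, which the simulation cannot settle.

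Named genes are, for each list and comparison, up to 3 higher and 3 lower members with the largest log2 fold among those past the threshold with the same sign in both lungs. Brd2, Brd3, Csf1r, Fcgr1, Fcgr2b, Fcgr3, Fcgr4, Tgfb1 and Spp1 are always named in macrophage comparisons, and Col1a1, Col3a1 and Postn in the fibroblast comparison. For levels over classes, the 3 members with the highest level in any class are named. Between the lungs, the 5 genes with the largest ratio each way are named among genes of at least 50 CPM in the higher lung. Some genes that these rules name are not reported here. Markers of other cell types and clusters given as examples were chosen after their values were seen. The 17 lists are BET proteins and elongation factors, Fc gamma receptors and signalling, profibrotic mediators, scar-associated macrophage genes, collagen and matrix, antigen presentation, interferon response, chemokines and cytokines, lipid handling, lysosome and phagocytosis, macrophage receptors and transcription factors, dissociation and immediate early genes, cell cycle, immunoglobulin, germinal centre and T follicular helper, T cell function, and sex-linked genes, which entered no test.

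Alternatives were DESeq2 size factors in edgeR, library size only, no gene filter, DESeq2 1.42.0, no block, the spread of all classes in 1 fit, resolutions 0.5 and 2, cells with at least 500 genes and 1000 UMIs, predicted doublets kept, features scaled over both libraries together, list genes allowed as features, UMIs split at random with clusters from one part and sums from the other, named cells only as denominator, lung 2 thinned by the ratio of the median UMIs per barcode, TMM-scaled levels, and each lung left out. A limit of 10% mitochondrial UMIs and the earlier naming forms were added after seeing the data. A planned comparison within interstitial macrophages by Lyve1 and Folr2 was not made, since they formed 1 cluster. The lungs are confounded with the library batch (pooled against single), and no test separates them. Python 3.11.15 and scikit-learn 1.9.0 were used.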

Results

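Gene expression was measured in single, fixed cells of mouse lung with chronic graft-versus-host disease (cGVHD). The group holds 2 lungs, of which lung 1 was part of a pooled library and lung 2 was a library of its own. The 12175 analysed cells of lung 1 held 48780215 UMIs, with a median of 3136 UMIs and 1577 genes per cell. The 10327 analysed cells of lung 2 held 113985087 UMIs, with a median of 5525 UMIs and 2594 genes per cell. The series title is about interstitial macrophages, BET inhibition and antibody-mediated fibrosis, so the comparisons set interstitial macrophages against the other macrophages and the monocytes of the same lungs, and a pair of fibroblast classes against each other. The arm of recipients of T cell-depleted bone marrow (TCD-BM) and the BET inhibitor arm were not analysed here, so all values describe cGVHD lungs and carry no background from healthy lung.

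T, NK and innate lymphoid cells, the lymphocytes of the T lineage and their innate relatives, made up 22.8% ± 1.26 of cells (SD, n = 2 lungs). Interstitial macrophages, which live in the tissue around airways and vessels and were led by C1qa, C1qb and C1qc, made up 4.62% ± 1.22, with 667 cells in lung 1 and 388 in lung 2. Alveolar macrophages, which clear surfactant in the air spaces, made up 9.95% ± 6.19. Adventitial fibroblasts, which surround vessels and airways, made up 1.90% ± 0.578, and alveolar fibroblasts, which support the gas exchange surface, made up 1.72% ± 1.60. Mast cells or basophils made up 0.594% ± 0.0190.

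Several classes differed between the lungs far beyond counting error. Classical monocytes made up 24.0% of lung 1 (95% exact interval 23.2 to 24.7) and 5.56% of lung 2 (5.12 to 6.02). Neutrophils made up 18.7% of lung 1 (18.03 to 19.4) and 5.66% of lung 2 (5.23 to 6.13). B cells made up 0.271% of lung 1 (0.187 to 0.380) and 6.66% of lung 2 (6.19 to 7.16). Surfactant-producing AT2 cells made up 0.485% of lung 1 (0.369 to 0.625) and 4.93% of lung 2 (4.52 to 5.36). Alveolar macrophages made up 5.58% of lung 1 (5.18 to 5.999) and 14.3% of lung 2 (13.7 to 15.02). Unnamed clusters held 10.2% of the cells of lung 1 and 6.10% of those of lung 2. The classical monocyte share of lung 2 depended on cluster resolution, features and naming: it was 0.436% at resolution 0.5, 0.223% with list genes allowed as features and 0.165% with names set against the mean of all other clusters.

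**Figure D1:**
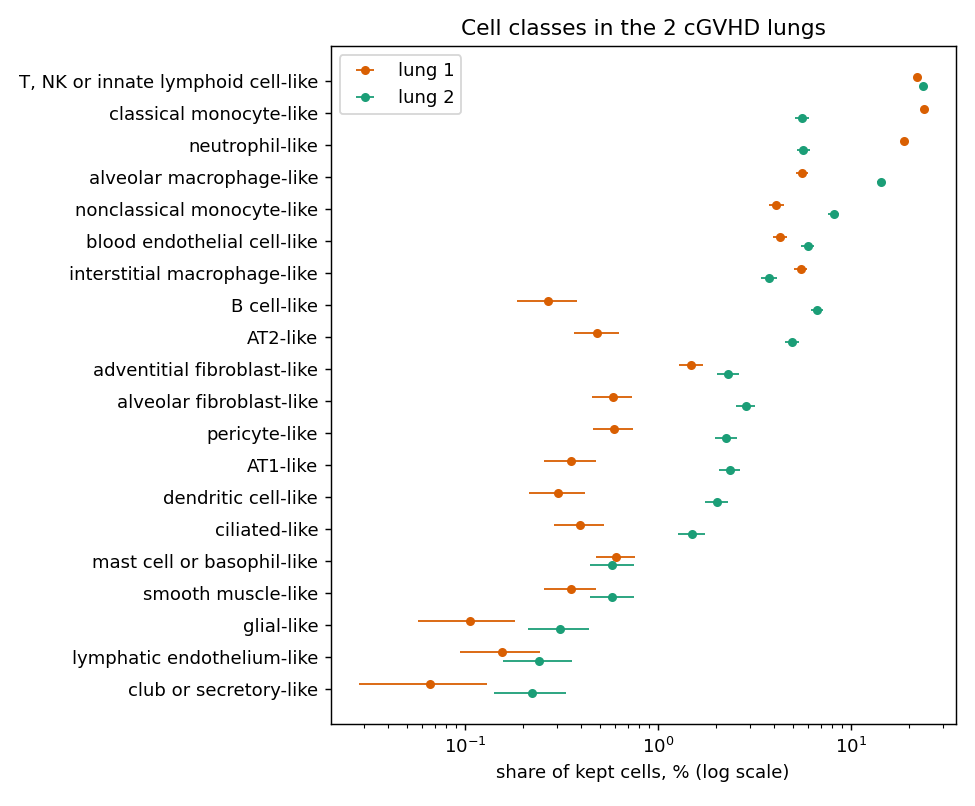
Share of kept cells (percent, log scale) of each cell class in lung 1 and lung 2, with exact 95% binomial intervals as bars. T, NK and innate lymphoid cells lie close together at 21.9% and 23.7%, while B cells lie at 0.271% and 6.66%.

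Interstitial macrophages were set against alveolar macrophages to ask how the macrophage named in the series title differs from the other resident macrophage of the same lungs. Alveolar macrophages came mostly from a different cluster in each lung. Cluster 9 held 677 cells of lung 1 and 7 of lung 2, and cluster 2 held 1 and 1419. Their Gpnmb level was 1245 CPM in lung 1 and 416 CPM in lung 2. The test called 12 of 13 interferon response genes, 7 of 12 antigen presentation genes, 16 of 27 chemokines and cytokines (4 lower) and 7 of 16 profibrotic mediators higher, and 9 of 16 lipid handling and 4 of 8 scar-associated genes lower. Cxcl13, a chemokine that attracts B cells, had 628 UMIs in interstitial and 3 in alveolar macrophages, a ratio of 766 (95% counting interval 261 to 3723). Spp1, which encodes osteopontin, was at 204 ± 57.6 CPM in interstitial and 1343 ± 156 CPM in alveolar macrophages (log2 fold -2.76, SE 0.16, edgeR adjusted p = 0.00592), lower in both lungs. Transcripts of the BET genes Brd2 and Brd3 differed by log2 folds of 0.08 and 0.09 and did not pass the test. The test covered 10867 genes, of which 1568 were higher and 1340 lower in interstitial macrophages.

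Of 13 interferon response genes tested, 12 were higher in interstitial macrophages, and 12 also when adjusted over the list alone. Rsad2, an antiviral enzyme, had a log2 fold of 4.16 (SE 0.75), Ifit1 of 3.85 (SE 0.52) and Usp18, a brake on interferon signalling, of 3.64 (SE 0.37). Of 12 antigen presentation genes, 7 were higher (10 adjusted over the list alone). The costimulatory receptor Cd40 had a log2 fold of 5.83 (SE 0.27), the MHC class II gene H2-Eb1 of 3.11 (SE 0.44) and Ciita, the master regulator of class II genes, of 2.42 (SE 0.37). Of 27 chemokines and cytokines, 16 were higher and 4 lower (19 and 4 adjusted over the list alone). Ccl8 and Ccl12, chemokines that attract monocytes, had log2 folds of 7.33 (SE 0.92) and 6.97 (SE 0.23), while Il18, Ccl3 and Ccl6 were lower at -3.79, -1.53 and -1.40. Neutrophil RNA was present in both classes at a level that went with the lung: S100a8 stood at 1602 and 112 CPM in interstitial macrophages and at 1144 and 103 CPM in alveolar macrophages of lung 1 and lung 2.

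Of 16 profibrotic mediators, 7 were higher (9 adjusted over the list alone). Mmp14, a membrane-bound matrix protease, had a log2 fold of 4.42 (SE 0.71), and Pdgfa and Pdgfb, growth factors for fibroblasts and pericytes, of 3.39 (SE 0.55) and 3.14 (SE 0.18). Tgfb1 had a log2 fold of -0.26 (SE 0.13) and did not pass. Of 8 scar-associated macrophage genes, 4 were lower, and 4 also adjusted over the list alone, among them Spp1, the tetraspanin Cd9 at -2.50 and Gpnmb at -2.25. Of 16 collagen and matrix genes, 2 were higher, Col4a2 at 1.13 and Sparc at 0.82, calls that ended under 5 and 4 alternatives; 0 were adjusted over the list alone, where edgeR gave 8 at an unadjusted p under 0.05 and DESeq2 called 1. Of 16 lipid handling genes, 9 were lower (9 lower and 1 higher adjusted over the list alone), with Fabp4, a fatty acid carrier, at -3.83, Pparg, the lipid-sensing regulator of alveolar macrophages, at -3.36 and the cholesterol exporter Abcg1 at -3.09. Of 13 lysosome and phagocytosis genes, 1 was higher and 5 were lower (2 and 6 adjusted over the list alone), with Gas6, a bridge between dying cells and phagocytes, at 3.56, and Ctsd, Mertk and Mrc1 at -2.17, -1.93 and -1.39.

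Of 11 BET and elongation genes, 1 was higher, also adjusted over the list alone: Hexim1, an inhibitor of the elongation kinase P-TEFb, at 0.87 (SE 0.10). Of 9 genes of Fc gamma receptors and signalling, 1 was higher, also adjusted over the list alone: Fcgr2b, the inhibitory receptor for IgG, at 957 ± 225 against 494 ± 96.4 CPM (log2 fold 0.93, SE 0.14, edgeR adjusted p = 0.0195). The activating receptors Fcgr1, Fcgr3 and Fcgr4 had log2 folds of 0.36, 0.45 and -1.08 and did not pass. DESeq2 called 2 genes of this list, and it called Fcgr4 lower (-1.08, DESeq2 adjusted p = 0.0366). Of 11 macrophage receptors and transcription factors, 4 were higher and 2 lower (5 and 3 adjusted over the list alone). The CSF1 receptor gene Csf1r stood at 1041 ± 126 against 310 ± 52.8 CPM (log2 fold 1.73, SE 0.13), with Maf at 4.01, Irf4 at 3.18, Bhlhe41 at -3.84 and Cebpb at -1.06. Of 11 dissociation and immediate early genes, 7 were higher (9 adjusted over the list alone), with the heat shock genes Hspa1a and Hspa1b at 4.03 and 3.75 and Egr1 at 2.13.

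Of 11 cell cycle genes, edgeR called 0, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. Of 4 immunoglobulin genes tested, 2 were higher (2 adjusted over the list alone), with Ighm at 3.53, where the B cell marker Cd79a stood at 3.27 and 28.97 CPM in interstitial and 2.48 and 6.77 CPM in alveolar macrophages of lung 1 and lung 2. Of 4 germinal centre and T follicular helper genes, 2 were higher (2 adjusted over the list alone), Bcl6 at 2.18 and Icos at 1.62. Of 9 T cell genes, 2 were higher, Cd4 at 1.88 and Lag3 at 1.55, and Havcr2 was lower at -1.07 (7 higher and 1 lower adjusted over the list alone). The T cell marker Cd3e stood beside them at 13.6 and 25.9 CPM in interstitial and 5.72 and 4.86 CPM in alveolar macrophages. The named calls that held under every alternative were those of Cxcl13, Ccl12, Cd40, Ciita, Rsad2, Usp18, Pdgfb, Maf, Irf4, Gas6, Hspa1a, Hspa1b, Egr1, Ighm and Bcl6 (higher) and of Spp1, Cd9, Il18, Pparg, Abcg1, Ctsd, Mertk and Bhlhe41 (lower); every other named call ended under at least 1. Without lung as a block, 486 genes were higher and 304 lower, 32 of the 50 named genes kept their side of the threshold, and calls went down to 6 interferon response, 3 antigen presentation, 8 chemokine and cytokine and 2 profibrotic genes higher and 5 lipid handling genes lower. The call of Gpnmb ended without the block (-2.48), at resolution 2 (-0.81) and with predicted doublets kept (-0.84), where under each of the last pair 2 scar-associated genes were higher, that of Csf1r with the spread of all classes (1.72), and that of Fcgr2b there (0.91), without the block (0.94) and with list genes allowed (0.70).

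**Figure D2:**
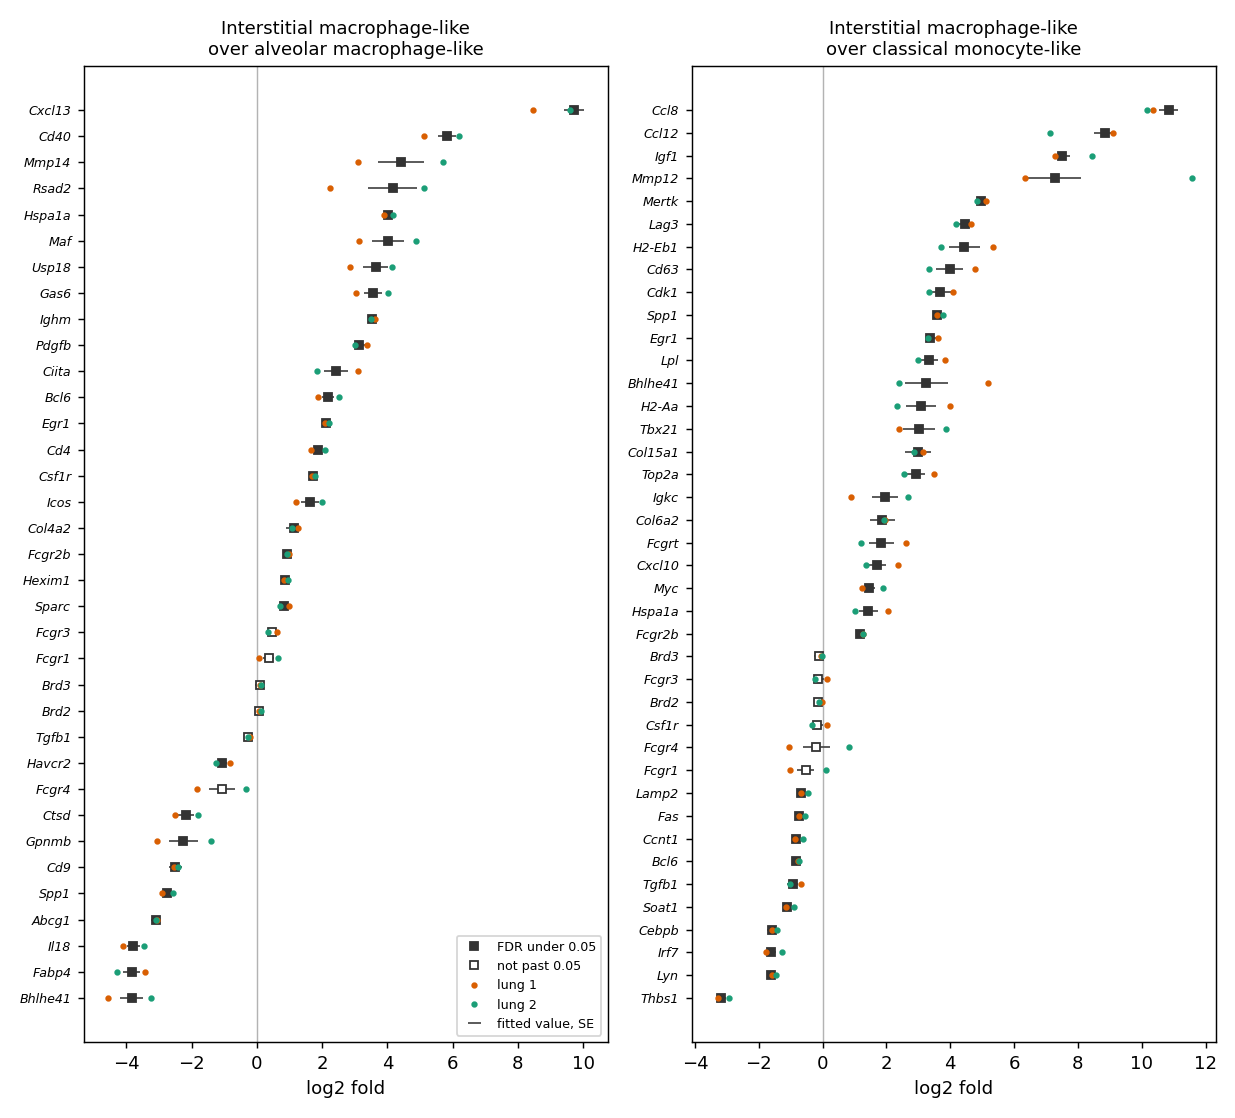
Log2 fold of interstitial macrophages over alveolar macrophages (left) and over classical monocytes (right), for the always-named genes and the highest and lowest other named gene of each list, with the edgeR value and its SE (squares and bars) and each lung alone (dots). Spp1 lies at -2.76 against alveolar macrophages and at 3.59 against classical monocytes; values for Cxcl13, Ccl8 and Ccl12 rest on few UMIs in the second class and depend on the prior count.

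Interstitial macrophages were next set against classical monocytes, the circulating cells that can replace tissue macrophages. Monocytes came from a different cluster in each lung: cluster 0 held 2919 cells of lung 1 and 17 of lung 2, and cluster 14 held 0 and 557, with a marker score of 1.93 and 3 markers over the limit, the fewest the naming rule takes. At resolution 0.5 lung 2 held 45 classical monocytes. The test called 10 of 16 profibrotic mediators (2 lower), 6 of 8 scar-associated genes, 8 of 12 antigen presentation genes, 20 of 27 chemokines and cytokines, 12 of 16 lipid handling genes (2 lower) and 8 of 11 cell cycle genes higher, and 7 of 11 BET and elongation genes lower (1 higher). Ccl8 had 1163 UMIs against 1, a ratio of 2350 (95% counting interval 421 to 92884), Cxcl13 had 628 against 1, a ratio of 1269 (227 to 50192), and Ccl12 had 627 against 3, a ratio of 422 (144 to 2053). Spp1 stood at 204 ± 57.6 against 15.7 ± 2.77 CPM (log2 fold 3.59, SE 0.14, edgeR adjusted p = 0.000720), higher in both lungs. The test covered 10630 genes, of which 1969 were higher and 1793 lower in interstitial macrophages.

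Of 16 profibrotic mediators, 10 were higher and 2 lower (12 and 2 adjusted over the list alone). Igf1, a growth factor for mesenchymal cells, had a log2 fold of 7.49 (SE 0.26), Pdgfc of 6.31 (SE 0.52) and Pdgfa of 4.62 (SE 0.62). Thbs1, which encodes the TGF-beta activator thrombospondin, and Tgfb1 itself were lower, at -3.19 (SE 0.17) and -0.94 (SE 0.17). Of 8 scar-associated genes, 6 were higher (7 higher and 1 lower adjusted over the list alone), with Mmp12, the macrophage elastase, at 7.27 and Cd63 at 3.99. Of 17 collagen and matrix genes, 7 were higher (7 adjusted over the list alone), with Col15a1 at 2.99, Col5a1 at 2.20 and Col6a2 at 1.87, all at low levels of 8.49 ± 2.37, 3.18 ± 0.517 and 6.51 ± 1.50 CPM in interstitial macrophages. DESeq2 called 2 genes of this list. The calls of Col15a1, Col5a1 and Col6a2 ended under 1, 10 and 5 alternatives, with log2 folds of 2.11, 0.02 and 2.11 at resolution 0.5. The fibroblast gene Dcn stood at 1.63 and 5.84 CPM in interstitial macrophages of lung 1 and lung 2. In monocytes it stood at 1.40 and 2.58 CPM. Of 12 antigen presentation genes, 8 were higher (8 adjusted over the list alone), with H2-Eb1 at 4.44, H2-Ab1 at 3.24 and H2-Aa at 3.08. Of 27 chemokines and cytokines, 20 were higher (22 adjusted over the list alone). Of 14 interferon response genes, 1 was higher, Cxcl10 at 1.72, and 2 were lower, Irf7 at -1.61 and Oasl2 at -0.87 (1 and 2 adjusted over the list alone); each of these calls ended without the block, and those of Irf7 (-0.64) and Oasl2 (-0.44) at resolution 0.5.

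Of 11 BET and elongation genes, 7 were lower and 1 higher (8 and 1 adjusted over the list alone), and 8 and 6 were lower with DESeq2 size factors and with library size only. Ccnt1, a subunit of P-TEFb, had a log2 fold of -0.83 and the acetyltransferase gene Ep300 of -0.60. Myc was higher at 1.46, and Brd2 and Brd3 had log2 folds of -0.15 and -0.11 and did not pass. Of 9 genes of Fc gamma receptors and signalling, 2 were higher and 3 lower (2 and 4 adjusted over the list alone). The IgG salvage receptor gene Fcgrt was at 1.84 and Fcgr2b at 1.19, while the kinase gene Lyn was at -1.62 and the shared signalling chain gene Fcer1g at -0.72. Fcgr1, Fcgr3 and Fcgr4 had log2 folds of -0.53, -0.14 and -0.19 and did not pass. Of 11 macrophage receptors and transcription factors, 4 were higher and 3 lower (4 and 3 adjusted over the list alone), with Bhlhe41 at 3.24, Irf4 at 2.64, Bhlhe40 at 2.15, Cebpb at -1.59, Csf2rb at -0.76 and Spi1 at -0.67; the calls of Bhlhe41, Cebpb, Csf2rb and Spi1 ended without the block and at resolution 0.5 (0.85, -0.89, -0.28 and -0.10). Csf1r had a log2 fold of -0.18 (SE 0.19) and did not pass.

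Of 16 lipid handling genes, 12 were higher and 2 lower (12 and 3 adjusted over the list alone), with Lpl, a lipase that frees fatty acids, at 3.33, Abca1 at 3.16, Fabp4 at 3.06 and Soat1 at -1.11. Of 13 lysosome and phagocytosis genes, 8 were higher and 1 lower (9 and 1 adjusted over the list alone), with Mertk and Axl, receptors for dying cells, at 4.95 and 4.21, Mrc1 at 4.64 and Lamp2 at -0.67. Of 11 cell cycle genes, 8 were higher (9 adjusted over the list alone), with Cdk1 at 3.69, Rrm2 at 3.29 and Top2a at 2.93; at resolution 0.5, 2 were higher and the call of Cdk1 ended (1.46). Cluster 18, with classical monocyte markers scoring highest, Mki67 at 496 CPM and 488 cells of lung 1, was left unnamed and is not part of the monocyte class. Of 11 dissociation and immediate early genes, 7 were higher (8 adjusted over the list alone), with Egr1 at 3.38, Jun at 1.68 and Hspa1a at 1.43. Of 4 germinal centre and T follicular helper genes, 2 were lower, Bcl6 at -0.85 and Fas at -0.74 (2 lower and 1 higher adjusted over the list alone). Of 8 T cell genes, 6 were higher (6 adjusted over the list alone), with Lag3 at 4.46, Cd4 at 3.18 and Tbx21 at 3.03; with predicted doublets kept Cd4 turned to -0.21 and Tbx21 fell to 0.22, and both calls ended there and at resolution 0.5, while Cd3e stood at 13.6 and 25.9 CPM in interstitial macrophages against 2.40 and 3.87 CPM in monocytes of lung 1 and lung 2.

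Of 3 immunoglobulin genes, 1 was higher (1 adjusted over the list alone), Igkc at 1.96, which turned negative under 5 alternatives, from -0.29 to -5.54. Cd79a stood beside it at 3.27 and 28.97 CPM in interstitial macrophages against 1.40 and 1.07 CPM in monocytes, and S100a8 at 1602 and 112 CPM against 1491 and 24.7 CPM. The named calls that held under every alternative were those of Ccl8, Ccl12, Cxcl13, Spp1, Mmp12, Cd63, Igf1, Pdgfa, Pdgfc, H2-Eb1, Irf4, Bhlhe40, Lpl, Abca1, Mertk, Axl, Mrc1, Rrm2, Top2a and Lag3, all higher; every other named call, which includes all lower ones, ended under at least 1. At resolution 0.5 the test called 478 genes higher and 106 lower, and without lung as a block 592 and 163; under both, all 7 lower calls of BET and elongation genes ended, as did those of Fcgr2b (1.29 and 1.20) and Tgfb1 (-0.17 and -0.91). The comparison could not be made with list genes allowed as features or with names set against the mean of all other clusters, since monocytes of lung 2 then fell under 30 cells.

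Adventitial fibroblasts were set against alveolar fibroblasts to ask which fibroblast of the cGVHD lungs carries matrix transcripts. The test called 9 of 23 collagen and matrix genes higher and 2 lower in adventitial fibroblasts, 9 of 14 interferon response genes higher, and 9 of 22 chemokines and cytokines higher and 3 lower. Alveolar fibroblasts came mostly from a different cluster in each lung: cluster 41, with Eln and Ccn2 among its leading genes, held 52 cells of lung 1 and 0 of lung 2, and cluster 24 held 19 and 294. Of the 238 adventitial fibroblasts of lung 2, 79 came from cluster 36, which held 3 cells of lung 1. Ccl7 and Timp1 were among the leading genes of cluster 36. With names set against the median, that cluster was not in the adventitial class. Col1a1, which encodes a chain of collagen type I, stood at 11201 ± 2523 against 4742 ± 1440 CPM (log2 fold 1.40, SE 0.36, edgeR adjusted p = 0.00226), higher in both lungs. Col3a1 stood at 16932 ± 3164 against 4792 ± 350 CPM (log2 fold 1.95, SE 0.37) and the small proteoglycan gene Dcn at 6126 ± 2011 against 65.6 ± 66.5 CPM (log2 fold 6.76, SE 0.45). The test covered 11145 genes, of which 945 were higher and 699 lower, 906 and 691 of them with the same sign in both lungs.

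Of 23 collagen and matrix genes, 9 were higher and 2 lower (11 and 3 adjusted over the list alone). Postn, which encodes the matrix protein periostin, had a log2 fold of 5.35 (SE 0.40), the elastin gene Eln of -1.03 (SE 0.33) and the matrix glycoprotein gene Tnc of -1.37 (SE 0.29). Cthrc1, a marker of matrix-producing fibroblasts, had 56 UMIs against 2, a ratio of 31.3 (95% counting interval 8.27 to 265). Of 14 profibrotic mediators, 6 were higher and 2 lower (7 and 2 adjusted over the list alone), with Pdgfc at 3.71, the protease inhibitor gene Timp1 at 2.56, Igf1 at 2.14, Ccn2 at -1.47 and Thbs1 at -1.19. Of 14 interferon response genes, 9 were higher (9 adjusted over the list alone), with Rsad2 at 2.59, Ifit1 at 2.33 and Gbp2 at 1.64. Of 22 chemokines and cytokines, 9 were higher and 3 lower (9 and 4 adjusted over the list alone), with Cxcl13 at 5.51, Ccl8 at 5.24, Ccl7 at 4.88, Ccl5 at -1.70, Cxcl14 at -1.67 and Ccl3 at -1.48. The calls of Ccl5, Cxcl14 and Ccl3 ended under 5, 5 and 8 alternatives, and that of Ccl8 with predicted doublets kept (2.55). Of 16 lipid handling genes, 1 was higher and 4 were lower (1 and 5 adjusted over the list alone), with Scd1 at 1.82, Cd36 at -2.37, Plin2 at -1.46 and Nr1h3 at -1.28.

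Of 12 antigen presentation genes, 1 was higher, B2m at 0.87, and 4 were lower (2 and 6 adjusted over the list alone), with H2-Eb1 at -2.34 and Cd40 at -1.80; DESeq2 called 1 gene of this list, and the calls of B2m and H2-Eb1 ended under 6 and 4 alternatives. The macrophage marker C1qa stood beside them at 3.53 and 4.09 CPM in adventitial and at 6.19 and 77.8 CPM in alveolar fibroblasts of lung 1 and lung 2. Of 6 scar-associated genes, 3 were higher (3 adjusted over the list alone), with Cd9 at 2.10, Gpnmb at 2.00 and Cd63 at 1.03. Of 12 lysosome and phagocytosis genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone), with Axl at 2.75, Ctsl at 0.95, Mertk at -1.32 and Cd68 at -0.91; DESeq2 called 1 gene of this list, and the calls of Ctsl, Mertk and Cd68 ended with DESeq2, without the block and with the spread of all classes. Of 11 macrophage receptors and transcription factors, 1 was higher and 1 lower, also adjusted over the list alone, Bhlhe40 at 1.05 and Maf at -1.44. Of 11 BET and elongation genes, Myc alone was higher, at 2.27, also adjusted over the list alone. In the same way 1 gene was higher in each of 3 lists: Fcgrt at 0.78 of 8 Fc gamma genes, Hspa1b at 1.76 of 11 dissociation genes and S1pr2 at 0.68 of 4 germinal centre genes, each also adjusted over the list alone. DESeq2 called 0 genes of the Fc gamma and germinal centre lists, and the calls of Fcgrt and S1pr2 ended under 5 and 9 alternatives.

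Of 4 immunoglobulin genes, 1 was lower, Igkc at -1.43 (2 lower adjusted over the list alone), with Cd79a at 14.1 and 25.3 CPM in adventitial and 6.19 and 35.9 CPM in alveolar fibroblasts. Of 8 cell cycle genes, edgeR called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Of 7 T cell genes, edgeR called 0, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. S100a8 stood at 1701 and 13.1 CPM in adventitial and at 1006 and 142 CPM in alveolar fibroblasts. Of the 42 named genes, 11 kept their call under every alternative that tested them, Dcn, Cthrc1, Timp1, Igf1, Cxcl13, Ccl7, Axl and Myc (higher) and Cd36, Plin2 and Cd40 (lower); every other named call ended under at least 1. The call of Col1a1 ended without lung as a block (1.40; 325 genes higher and 204 lower) and with the spread of all classes (1.38; 536 and 361), where 1 and 2 of the interferon response genes stayed higher and the call of Col3a1 (2.02) ended under the latter, and DESeq2 called 379 and 313 genes, 3 of them interferon response genes. At resolution 0.5, where 1506 genes were higher and 1588 lower, Postn turned to -0.03. Pericytes had no named cluster there, and the alveolar fibroblast class was larger. The calls of Eln (-0.12), Tnc (-0.54), Ccn2 (-0.45) and Thbs1 (-0.37) ended at that resolution, without the block and with the spread of all classes. That of Eln also ended with stricter cells (-0.57), doublets kept and list genes allowed (-0.91).

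**Figure D3:**
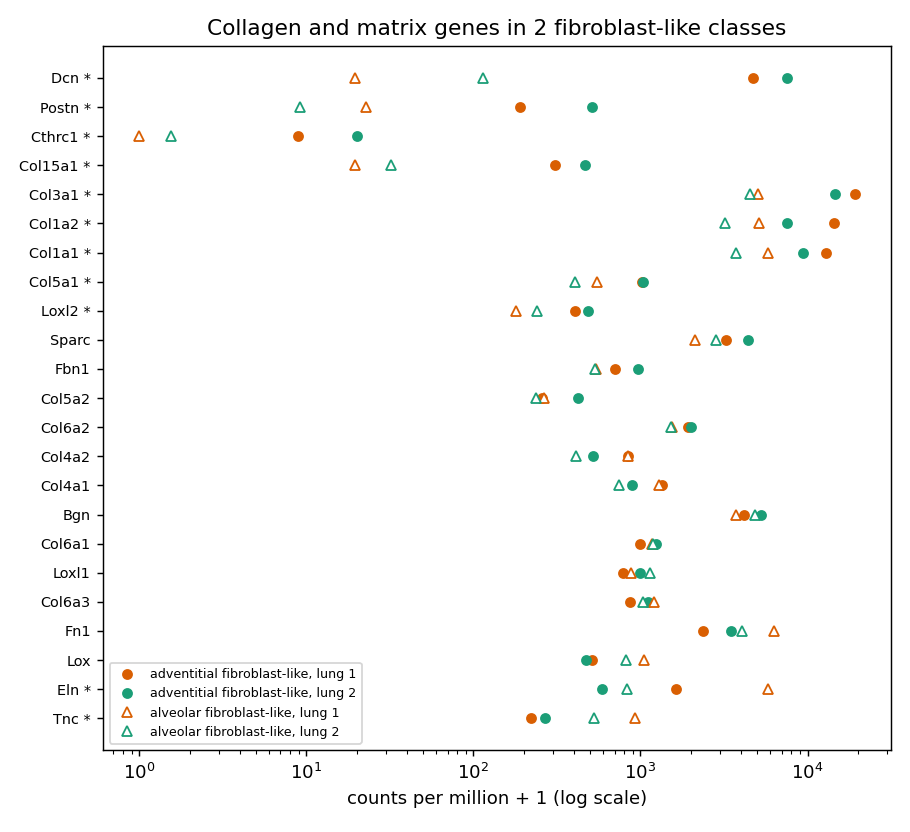
Level of the collagen and matrix list in adventitial fibroblasts (circles) and alveolar fibroblasts (triangles) of each lung, in CPM plus 1 on a log scale, ordered by log2 fold, with stars for genes past the edgeR threshold. Dcn lies at 6126 ± 2011 against 65.6 ± 66.5 CPM.

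Levels of the list genes over 17 classes show which cells of these lungs carried each transcript, and 133 of 218 measured list genes peaked in the same class in both lungs. Interstitial macrophages held the highest mean level of 17 genes, 10 of which follow here with that class highest in both lungs: Fcgr2b, Mmp12, H2-DMb1, Ciita, Ccl8, Ccl12, Ccl24, Il10, Abca1 and Apoe. The MHC class II genes H2-Aa, H2-Ab1 and Cd74 also peaked there on average, at 9202 ± 1323, 10068 ± 3596 and 38544 ± 11228 CPM, but were highest in dendritic cells in lung 2. Alveolar macrophages held the highest levels of Spp1 (1343 ± 156 CPM), Cd9 (5425 ± 1014 CPM), Lgals3 (3475 ± 469 CPM), Ctsd (2180 ± 50.6 CPM) and Ctss (10200 ± 2874 CPM). Nonclassical monocytes, which patrol vessel walls, held the highest levels of Csf1r (1969 ± 58.6 CPM), Fcgr4 (1013 ± 541 CPM), Fcer1g (3709 ± 1276 CPM), Lyn (1020 ± 361 CPM) and Ctsb (3096 ± 451 CPM). Classical monocytes held the highest level of Tgfb1 (1069 ± 5.03 CPM), and neutrophils that of Il1b (11233 ± 10136 CPM). The mean levels of Fcgr1 (120 ± 43.5 CPM) and Fcgr3 (570 ± 133 CPM) were highest in classical monocytes, with interstitial macrophages highest in lung 2 and in lung 1.

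Brd2, Brd3 and Hexim1 peaked in different classes in the 2 lungs, and interstitial macrophages held 278 ± 52.6 and 28.7 ± 1.64 CPM of Brd2 and Brd3. Col1a1, Col1a2 and Col3a1 peaked in adventitial fibroblasts in both lungs. Postn was highest on average in pericytes (611 ± 66.8 CPM), the contractile cells around capillaries, and Thbs1 (5233 ± 3517 CPM) and Fn1 (5161 ± 1596 CPM) in alveolar fibroblasts. The pericyte class may be mixed, since capillary endothelium markers scored 2.23 beside 3.41 for pericyte markers. Named against the median, its cluster had markers of alveolar fibroblasts and endothelium and stayed unnamed. At resolution 2 the class held 45 and 65 cells, against 72 and 232 here. Mast cells or basophils held the highest levels of Ccl3 (13605 ± 4474 CPM), Ccl4 (17607 ± 6141 CPM) and Gzmb (1892 ± 1335 CPM). AT2 cells held the highest levels of Scd1 (5628 ± 1031 CPM) and Npc2 (3648 ± 212 CPM). T, NK and innate lymphoid cells held the highest levels of Icos (813 ± 170 CPM), Cd4 (481 ± 114 CPM), Ctla4 (896 ± 166 CPM), Rrm2 (284 ± 180 CPM) and Pcna (667 ± 9.64 CPM), and B cells those of Igha (16190 ± 11365 CPM), Igkc (59600 ± 51024 CPM) and Cxcr5 (692 ± 200 CPM). Blood endothelial cells held the highest level of Irf1 (978 ± 307 CPM). The other named genes, Syk, Gbp2, Klf4, Cebpb, Fos, Fosb, Egr1, Mki67 and Bcl6, peaked in different classes in the 2 lungs.

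**Figure D4:**
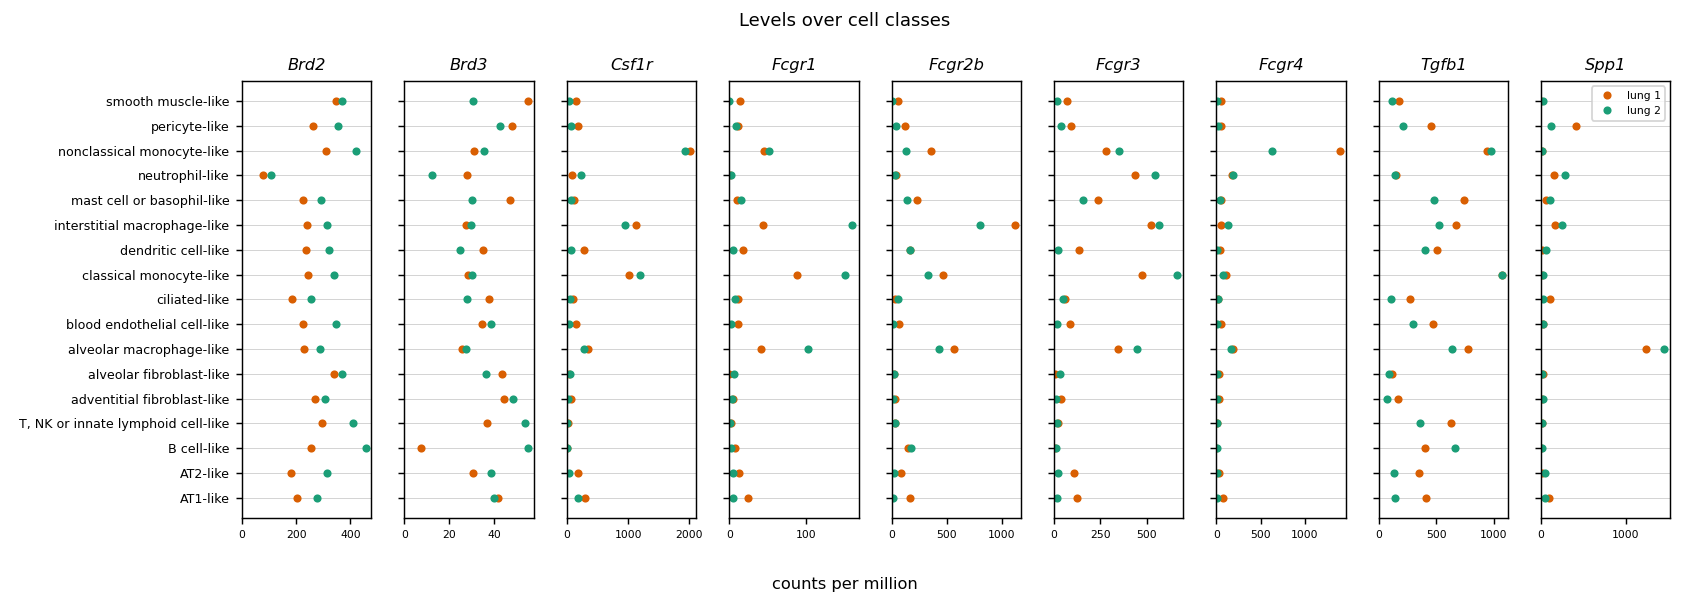
Level (CPM, linear axes that differ between panels) of the always-named macrophage genes in each class with at least 30 cells per lung, with 1 dot per lung. Spp1 stands out in alveolar macrophages at 1343 ± 156 CPM and Csf1r in nonclassical monocytes at 1969 ± 58.6 CPM.

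The lungs were set side by side as whole-lung sums, as values with no test, since each is a single library. Among 5547 genes of at least 50 CPM in the higher lung, 72 were over 4-fold higher in lung 1 and 318 in lung 2. Lung 1 was higher in Camp, Ngp and Ltf, genes of maturing neutrophil granules, with log2 ratios of 11.45 (95% counting interval 10.98 to 11.95), 8.53 (8.44 to 8.63) and 7.40 (7.28 to 7.52), and in the basophil protease gene Prss34 and the antibody gene Ighg1, with 7.48 (7.19 to 7.78) and 8.04 (7.67 to 8.44). Of the 6522 Ighg1 UMIs of lung 1, 6454 lay in B cells, where 1 barcode held 85.9% of them, so the Ighg1 interval, which takes UMIs as independent, is too narrow. In lung 2, 1 cell of cluster 8 held 25 of the 37 Camp and 445 of the 919 Ngp UMIs, so their intervals are too narrow as well. All other intervals here also take UMIs as independent, and the spread of those UMIs over cells is not given. Lung 2 was higher in the antibody genes Igkv15-103, with 1 UMI in lung 1 and 6111 in lung 2 (log2 ratio -11.35, -16.66 to -8.87), Iglc1 (-6.27, -6.69 to -5.87) and Ighd (-6.26, -6.74 to -5.83). It was also higher in the airway secretory gene Scgb3a2 (-4.66, -4.93 to -4.41) and the AT2 gene Lamp3 (-4.65, -4.79 to -4.51). Brd2 and Brd3 had log2 ratios of -0.55 and -0.24, Fcgr1, Fcgr2b, Fcgr3 and Fcgr4 of -0.00, 0.94, 0.80 and 0.67, and Csf1r, Tgfb1 and Spp1 of 0.92, 0.79 and -0.96. Col1a1, Col3a1 and Postn had log2 ratios of -0.75, -0.69 and -2.93. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 UMIs in both lungs, and Xist is not on the panel.

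Genes named whatever their result were looked up in GENCODE by identifier. On mm10, Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050, Fcgr2b (ENSMUSG00000026656) on chromosome 1 from 170958617 to 170976547, Csf1r (ENSMUSG00000024621) on chromosome 18 from 61100598 to 61132149, Tgfb1 (ENSMUSG00000002603) on chromosome 7 from 25687002 to 25705077, Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94936224 to 94953042 and Postn (ENSMUSG00000027750) on chromosome 3 from 54361109 to 54391037.

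The barcode list of the TCD-BM arm held 15829 called cells, all with probe barcode BC002. The 13578 named barcodes of lung 1 all carried BC003. No expression was compared between arms.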

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

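The mitochondrial limit and the earlier naming forms were chosen after seeing the data; the other alternatives were planned. Under every alternative run with a test, no reversal was counted for all 50 named genes of interstitial against alveolar macrophages. The same held for 60 of 62 against classical monocytes and 41 of 42 of the fibroblast comparison. A gene that passed in neither run counted as unchanged whatever its sign, so these counts do not show the direction of uncalled genes. Of the named genes, 28, 25 and 11 kept their side of the threshold throughout. With 1 lung left out there is no test. Then 10 of 100, 41 of 124 and 30 of 84 values lay over 1 SD from the fitted log2 fold. That SD comes from the same 2 lungs, and the folds of 1 lung use library size without TMM scaling. These counts therefore do not measure how far a value depends on 1 lung. The direction of these values is mostly fixed by the rule for the genes named. Without lung as a block, the genes higher and lower were 486 and 304 for interstitial against alveolar macrophages, 592 and 163 against classical monocytes, and 325 and 204 for the fibroblasts. With the spread of all classes, 1050 genes were lower than in monocytes, and the fibroblasts gave 536 and 361. DESeq2 gave 379 and 313 for the fibroblasts. At resolution 0.5 the monocyte comparison gave 478 and 106 and the fibroblasts 1506 and 1588; with at least 500 genes and 1000 UMIs per cell, 1187 genes were lower in adventitial fibroblasts. Of fibroblast genes called lower at these last settings, 29 and 18 had been called higher before. Of genes called lower than in monocytes, 10 with doublets kept and 1 with UMIs split had been called higher before. Against monocytes, Igkc reversed to -5.12 at resolution 0.5, -4.31 with the stricter cell filter, -0.29 with doublets kept, -5.54 with UMIs split and -5.06 when named without a second search, and Cd4 to -0.21 with doublets kept. Postn reversed to -0.026 in the fibroblasts at resolution 0.5. There, pericytes, the class with the highest mean Postn level, had no named cluster, and the alveolar fibroblast class was larger. Mean shares moved beyond 1 SD for T, NK and innate lymphoid cells (24.8% of named cells, 21.4% with doublets kept), alveolar fibroblasts (4.30% at resolution 0.5), blood endothelial cells (6.77% at resolution 0.5, 6.71% scaled together), interstitial macrophages (7.35% with list genes allowed), mast cells or basophils (0.648% of named cells, 0.568% with the stricter filter) and nonclassical monocytes (9.001% at resolution 0.5); the other 244 share values stayed within 1 SD. The cause was not tested in any of these. The SD comes from the same 2 lungs, so a share from 1 lung alone always lies within it. The mean classical monocyte share stayed within it even where lung 2 fell to 0.165%, with names against the mean. Not counted here are shares with lung 2 thinned and clusters and names made again. There, the cluster named club or secretory made up 2.66% and 0.909% of lung 1 and lung 2, against 0.0657% and 0.223%. It held 324 and 91 cells, and classical monocyte markers scored second in it. Cluster 20 of the main run, with 315 and 102 cells, stayed unnamed for markers of classical monocytes and erythroid cells. The rise may therefore not be one of club cells, and whether these clusters share cells was not examined. With the same thinning, blood endothelial cells made up 4.84% and 9.41%, against 4.30% and 5.97%. Library size alone moved the median log2 fold of all fibroblast genes to -0.09 from 0.02. The monocyte comparison gave no value with list genes allowed or names against the mean, and AT1, pericyte and club cells had no named cluster under some settings. TMM-scaled levels gave 148 genes peaking in the same class in both lungs and 20 peaking in interstitial macrophages. In simulated counts a 2-fold change was found in 24.7% of fibroblast genes.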

Other observations

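T cells of these lungs formed clusters with distinct cytokine transcripts; the clusters and genes given here were chosen after their values were seen. In cluster 3, Il17a, the cytokine of type 17 T cells, stood at 832 CPM and Il5 at 22.2 CPM in the 1113 cells of lung 1 (9.14% of its cells), while its 81 cells of lung 2 held Il17a at 154 CPM and Il5 at 439 CPM. Cluster 29 of lung 2 (253 cells, 2.45%) held Il17a at 1173 CPM and Il17f at 454 CPM. Foxp3, the regulator of suppressive T cells, stood at 927 CPM in the 170 cells of lung 1 and 845 CPM in the 211 cells of lung 2 of cluster 22, with the checkpoint gene Ctla4 at 2920 and 3484 CPM. A cycling cluster, 28, held Foxp3 at 378 and 300 CPM and Mki67 at 809 and 1583 CPM. CD8 T cells with Ifng were cluster 11 in lung 1 (590 cells, Cd8a at 736 CPM, Ifng at 438 CPM, Gzmb at 1626 CPM) and cluster 21 in lung 2 (413 cells, Cd8a at 536 CPM, Ifng at 452 CPM). Cluster 4, with Lef1, a gene of naive T cells, at 1147 CPM, held 1132 cells of lung 2 (10.96%) and 5 of lung 1. NK cells (cluster 27) held Gzma at 12797 and 10904 CPM and made up 0.246% and 2.41% of the lungs.

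Mast cells or basophils (cluster 33) held the type 2 cytokine genes Il4, at 1686 and 781 CPM, and Il13, at 1498 and 1716 CPM. Neutrophils came as a cluster with granule genes in lung 1 (cluster 8, 688 cells, Ngp at 38194 CPM, Camp at 14005 CPM, Ltf at 12477 CPM) beside cluster 1 of lung 1, with Ngp at 7301 CPM and Il1b at 6109 CPM, and cluster 15 of lung 2, with Ngp at 223 CPM and Il1b at 18842 CPM. An unnamed cluster, 18, with Elane, Mpo and Prtn3, genes of granulocyte-monocyte progenitors, at 786, 835 and 1263 CPM, held 488 cells of lung 1 and 2 of lung 2. An unnamed cluster, 19, led by the platelet genes Ppbp (1749 and 903 CPM) and Pf4 (610 and 352 CPM), held 130 and 359 cells. Dendritic cells of cluster 40 (21 and 31 cells) held Ccr7, a receptor of migrating dendritic cells, at 2893 and 7893 CPM, and the type 1 cytokine gene Il12b at 294 and 4071 CPM. Interstitial macrophages held Lyve1, Folr2, Timd4 and Cd163, genes of perivascular resident macrophages, at 63.5, 34.6, 17.7 and 29.2 CPM in lung 1 and 37.6, 96.4, 56.0 and 38.5 CPM in lung 2.

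Of the tests that follow, those of depth with clusters made again, library batch, free RNA, admixed cells and a gene-wise library effect were chosen after the result was seen, and the patterns and their genes were picked from the values. Classical monocytes and neutrophils made up larger shares of lung 1 than of lung 2, with ratios of 4.31 and 3.30. With lung 2 thinned by the ratio of the median UMIs per barcode and filtered again, but cluster names kept, the smaller ratio was 3.25; it could not have fallen below 3.20, so this value does not test depth. With clusters and names made again from the thinned counts the ratios were 3.57 and 3.41, and with predicted doublets kept 3.11 and 3.38. Among the called cells, neither thinning by the ratio of medians nor keeping doublets thus removed the difference. Barcodes had been called as cells before the thinning, so an effect of depth on cell calling was not tested. Depth also stayed unequal within classes, with medians of 3780.5 UMIs in the main monocyte cluster of lung 1 and 4695 in that of lung 2. Over all processing choices the monocyte ratio ran from 3.11 to 146, with 3.81 for the stricter cell filter, 65.8 at resolution 0.5 and 107 with list genes allowed. Each library batch holds 1 lung of this group, so the pooled and the single library cannot be told apart from a difference between the animals, and no biological explanation was tested.

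In lung 1, the 33 B cells held 6454 UMIs of Ighg1, the heavy chain of class-switched IgG1 antibody, at 46757 CPM against 16.7 CPM in lung 2. Free RNA would give other classes a like level, but the level in B cells was 52929 times the median of the other classes (0.883 CPM). A single cell or droplet is a candidate explanation for most of this level, since 1 barcode held 85.9% of these UMIs. In all, 7 of the cells held at least 10. The UMIs outside that barcode still exceeded the 45 Ighg1 UMIs in the 688 B cells of lung 2. That barcode alone thus does not account for the whole difference between the lungs. No biological explanation was tested.

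Alveolar macrophages of lung 1 held more Arg1 (316 against 1.91 CPM), Gpnmb (1245 against 416 CPM), Mmp12 (599 against 28.6 CPM) and Apoe (874 against 36.1 CPM) than those of lung 2. The class is mostly a different cluster in each lung, since cluster 9 held 677 cells of lung 1 and 7 of lung 2, and cluster 2 held 1 and 1419. The C1q genes allow a share of 5.35% interstitial macrophage RNA among them, and 4 of the 4 genes lay above 2 times the level that this share brings, so admixed cells do not account for the whole difference. A gene-wise effect of the library would act in other classes too, where the median log2 ratio over 16 classes was 2.86 for Arg1 and 1.13 for Mmp12, and 4 of the 4 genes exceeded their median by more than 1, so such an effect does not account for the whole difference but is not excluded for a part. The lungs differ in library batch, with 1 lung in each, so batch and animal cannot be told apart, and no biological explanation was tested.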
